A study of Sus scrofa with 8 samples.

How the data were processed

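Right ventricular tissue of PKP2 heterozygous knockout and wild-type pigs was profiled by RNA sequencing in 8 libraries, 4 per group, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, 1 µg per sample entered an Illumina library preparation, and 150 bp paired reads were sequenced on a NovaSeq instrument. Reads were aligned with HISAT2 2.0.5, per the labels' protocols and the submitters' processing notes. The program that counted fragments, the annotation and the normalisation are not given in the sources used here.

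The deposited table holds FPKM values (fragments scaled by gene length and library size) for 30550 genes, with gene names, coordinates and lengths. Of these, 30335 matched the RefSeq table of Sscrofa11.1 and had the same start and end there; 215 did not match. FPKM multiplied by gene length was a whole multiple of 1 step in each library for 100% of values, within 0.01 fragments, which gave back the fragments per gene. The library factors contained in the deposited FPKM values equal median-of-ratios factors computed from these fragments over 15715 genes above 0 in every library, with a largest relative difference of 4.4e-16. FPKM sums therefore differ between libraries, and levels are relative to the median gene.

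Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested (10757 genes), whatever the group of the libraries. Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with a variance trend, no replicate term, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Fold changes on the log2 scale include the pseudocount of 1 and understate changes of low genes; folds without it are ratios of mean FPKM. PKP2 was also compared with an exact permutation test over 70 relabellings. Of 43 gene lists, 36 with at least 5 tested genes entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. The remaining 7 lists, of T and NK, B and plasma, neutrophil and mast, mesothelial, erythroid, skeletal muscle and sex-linked genes, had 0 to 3 members past the filter and entered no test with it. The lists, tests and alternatives were fixed before the data were examined. List members were matched to the table by symbol (986 entries), and otherwise by older symbols (20), RefSeq synonyms (2) or the protein annotation in the table (17); 28 had no match, and these matching rules were set after the table was seen.

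Genes named in the text follow a rule set beforehand: the desmosomal genes PKP2, JUP, DSP, DSG2 and DSC2; the 10 largest changes in each direction among called genes with a symbol and groups that do not overlap; up to 4 members with the smallest p of each list described; and the markers with the highest mean FPKM of a cell type described. Other genes were named after their values were seen. That placeholder names starting with LOC are not symbols was decided after the data were seen.

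Fragments were simulated for the real genes, with 200 genes changed and the autophagy and lysosome list shifted as a whole, and 10786 genes passed the filter. The same fit of 4 PKP2_het against 4 WT libraries recovered 72.3% of tested 2-fold changes and 96.9% of tested 4-fold changes. With the shifted list left out, 4.71% of called genes were unchanged ones. The simulation drew genes independently and does not test how camera behaves on correlated genes. Alternatives covered pseudocounts of 0.1 and 0.5, filters, scalings, library weights, robust variances, voom on the recovered fragments, a replicate term, and leaving out each library. Leaving out both PKP2_het replicates 3 and 4 and removing a trend with gene length were added after seeing the data.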

Results

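RNA was sequenced from right ventricular heart tissue of pigs (Sus scrofa) with a heterozygous knockout of PKP2 and of wild-type pigs. PKP2 encodes plakophilin 2, a protein of the desmosomes that join heart muscle cells, and the series presents the animals as a model of arrhythmogenic cardiomyopathy, an inherited heart muscle disease. The labels give 4 libraries of the heterozygous knockout (PKP2_het) and 4 wild-type libraries (WT). They also name cardiomyocytes as the cell type, whereas the protocol describes whole tissue. The deposited FPKM values correspond to between 23637697 and 31313628 fragments assigned to genes per library. No label says that each library came from a separate animal, so the p-values measure the spread between these libraries.

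The PKP2 transcript was lower in PKP2_het tissue. Its level was 39.2 ± 9.99 FPKM (SD, n = 4) in PKP2_het and 62.2 ± 8.17 FPKM (SD, n = 4) in WT, which is 62.9% of the WT mean. The highest PKP2_het library, at 45.9 FPKM, lay below the lowest WT library, at 52.9 FPKM. The log2 fold change was -0.69 with a standard error of 0.20, and the two-sided exact permutation p was 0.0286, the smallest that 70 relabellings of the 8 libraries can give. Across all genes the limma adjusted p was 0.164, so PKP2 was not among the genes called genome-wide. PKP2 (gene 100526169) lies on chromosome 5 of Sscrofa11.1, from 41424687 to 41509590. PKP2_het replicate 3 had the lowest level, 24.6 FPKM. Without it the PKP2 log2 fold change was -0.48 with a standard error of 0.12, and the PKP2_het mean was 70.7% of the WT mean. The exact permutation p was then 0.0571 and the limma adjusted p 0.0732, and the groups still did not overlap.

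The other desmosomal genes did not differ by more than the spread between libraries. The log2 fold change was -0.13 ± 0.16 (SE) for JUP (plakoglobin), -0.42 ± 0.50 for DSP (desmoplakin), -0.06 ± 0.32 for DSG2 (desmoglein 2) and 0.15 ± 0.28 for DSC2 (desmocollin 2). PKP2_het replicate 3 was the lowest library for all of these genes, with DSP at 9.998 FPKM against 50.8 to 58.3 FPKM in the other PKP2_het libraries. Without that library DSC2 was higher in PKP2_het, with a log2 fold change of 0.48 and a limma adjusted p of 0.0475. In the list of desmosomal and intercalated disc genes, PKP2 left out, 0 of 19 members passed the limma threshold, adjusted over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. This was TJP1, which encodes the tight junction protein ZO-1, with a log2 fold change of -0.37 and a limma adjusted p of 0.360. CTNNB1 (beta-catenin) had a log2 fold change of -0.34 and a limma adjusted p of 0.526, and -0.13 without PKP2_het replicate 3. Of the 19 members 12 had a negative log2 fold change with all libraries, whereas 14 were positive without that library.

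**Figure D1:**
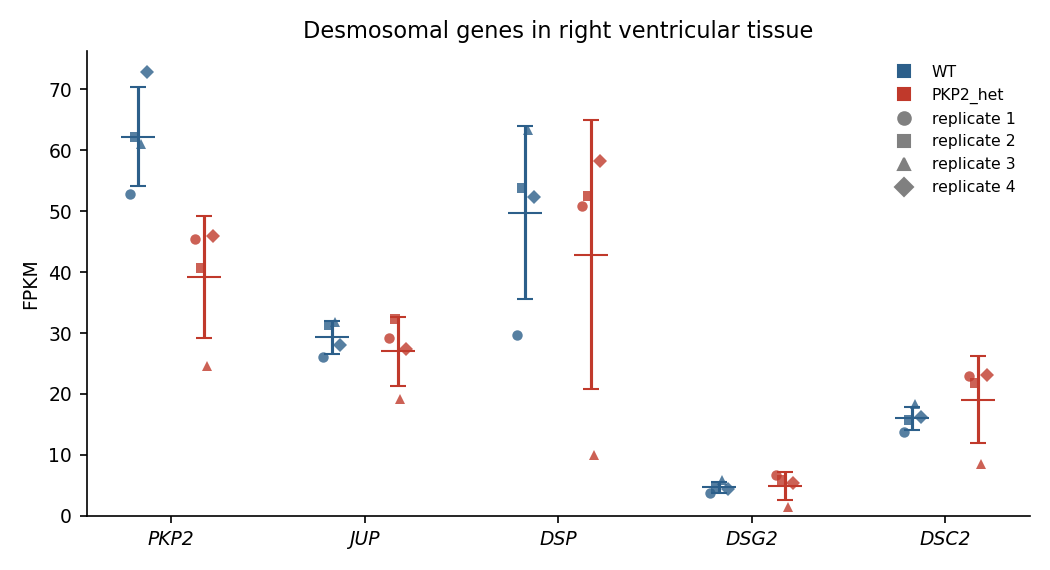
FPKM (vertical axis) of PKP2 and 4 other desmosomal genes in each WT (blue) and PKP2_het (red) library; symbols mark the replicate number, and bars give the mean and SD of 4 libraries. PKP2 is the gene whose groups do not overlap, and PKP2_het replicate 3 (triangles) is the lowest PKP2_het library for every gene shown.

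Genome-wide, 124 genes were higher and 76 lower in PKP2_het tissue among 10757 tested (limma, Benjamini-Hochberg adjusted p threshold 0.05). The labels give no litter or ancestry, so for these genes a genetic background that differs between the groups cannot be told apart from the knockout. Among the genes with a symbol that rose most were TSPO, a cholesterol-binding protein of the outer mitochondrial membrane, CYP27A1, a mitochondrial sterol hydroxylase, and APOE, the lipid carrier apolipoprotein E. TSPO rose from 31.3 ± 13.4 to 112 ± 23.6 FPKM (SD, n = 4), CYP27A1 from 6.85 ± 2.85 to 21.8 ± 3.76 FPKM and APOE from 3.48 ± 0.992 to 12.1 ± 3.63 FPKM. The extracellular proteins PTN (pleiotrophin), NPNT (nephronectin) and OLFM1 (olfactomedin 1) also rose, by 8.91-fold, 4.10-fold and 3.71-fold. IGSF5 rose by 5.98-fold, LACTB2 by 2.87-fold, the alcohol dehydrogenase gene ADH1C by 5.35-fold and the antimicrobial peptide gene DEFB1 by 8.73-fold. Adjusted p-values of these 10 genes (limma) ran from 0.000134 for PTN to 0.0159 for TSPO. The WT means of PTN, DEFB1 and ADH1C were only 0.402, 0.469 and 0.597 FPKM, so the size of their folds is uncertain. TSPO lost its call in 3 of 22 alternative settings (adjusted p up to 0.0621), and CYP27A1, LACTB2, OLFM1 and ADH1C each lost it in 1, at adjusted p of 0.149, 0.228, 0.0657 and 0.0509.

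FRZB, a secreted antagonist of Wnt signalling, and P2RY1, a receptor for extracellular ADP, were among the genes that fell most. FRZB was at 47.5 ± 20.8 FPKM in WT and 6.26 ± 3.06 FPKM in PKP2_het (SD, n = 4), and P2RY1 at 11.5 ± 3.90 and 0.789 ± 0.0998 FPKM. MYL1, a myosin light chain of fast skeletal muscle, was at 27.0 ± 21.5 FPKM in WT and 1.86 ± 0.894 FPKM in PKP2_het, with a limma adjusted p of 0.0328 that was lost in 10 of 22 alternative settings. GNLY (granulysin, a cytolytic protein of lymphocytes) was 10.2-fold lower, DHRSX, annotated on chromosome Y, 7.30-fold lower and GGA1, which sorts cargo at the trans-Golgi network, 4.22-fold lower. The PKP2_het means of GNLY and DHRSX were low, at 0.641 and 0.882 FPKM. SHD was 5.11-fold, TSPAN2 4.76-fold, IGSF23 4.54-fold and PREPL 2.96-fold lower, with IGSF23 losing its call in 1 of 22 alternative settings (limma adjusted p = 0.0513). Leaving out PKP2_het replicate 3 raised the counts to 195 higher and 119 lower, and 119 of the 124 higher and 72 of the 76 lower calls were kept. Without WT replicate 4, 73 and 39 of them were kept.

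**Figure D2:**
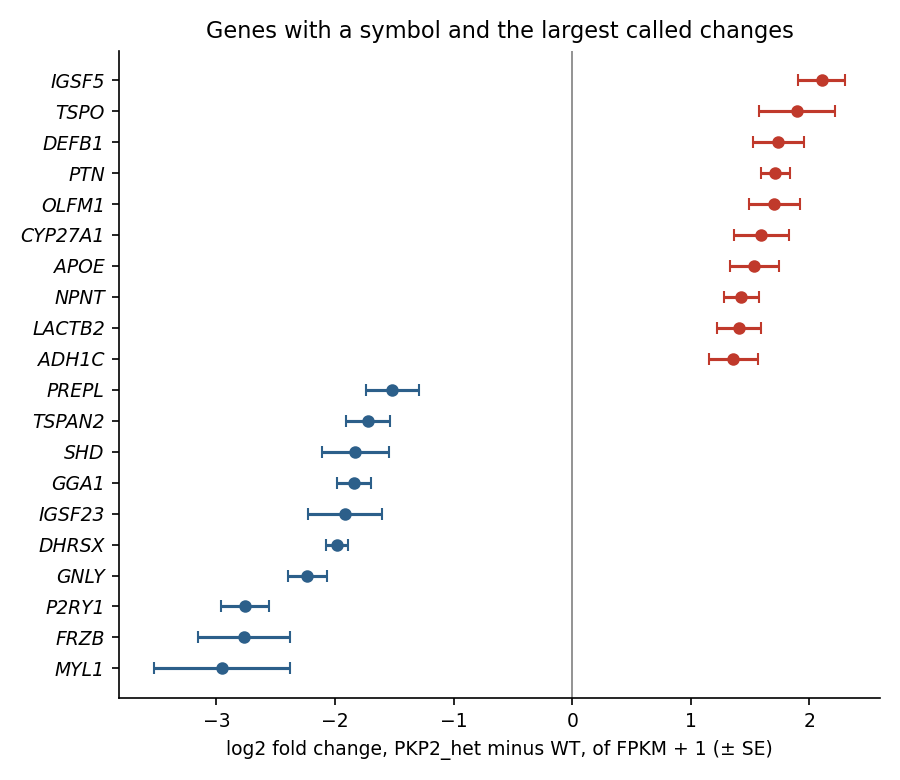
Log2 fold change with its standard error (horizontal axis, PKP2_het minus WT on the scale of FPKM + 1, 4 libraries per group) of the 20 genes with a symbol and the largest called changes. MYL1, FRZB and P2RY1 lie furthest below 0, and IGSF5, at 2.10, furthest above.

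Several of the largest differences were in genes without an established symbol, named here after their values were seen. A liver carboxylesterase gene (LOC100736962) on an unplaced scaffold was at 168 ± 36.7 FPKM in PKP2_het and 2.54 ± 2.415 FPKM in WT (SD, n = 4). A neighbouring carboxylesterase-like pseudogene (LOC110255234) was at 57.9 ± 26.0 and 4.70 ± 1.09 FPKM, and fragments can be shared between such copies. A V segment of an antigen receptor (LOC110258689) was at 0.161 ± 0.282 FPKM in PKP2_het and 20.7 ± 6.17 FPKM in WT. Another V segment (LOC110258687) had 0 fragments in all 4 PKP2_het libraries and 4.01 FPKM in WT, at least 64-fold lower when 3 fragments over the group are taken as the floor.

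Genes of electrical conduction, calcium handling and contraction showed few calls. Of 21 ion channel and conduction genes, 1 rose: KCND3, which encodes a channel of the transient outward potassium current, went from 0.838 ± 0.167 to 1.53 ± 0.139 FPKM (SD, n = 4; limma adjusted p = 0.0386). KCND3 lost its call in 11 of 21 alternative settings. KCNE1, a potassium channel subunit, had a log2 fold change of 0.49 and a limma adjusted p of 0.190. Of 23 calcium handling genes 0 were called by limma, 1 had an unadjusted p under 0.05, and 20 had a negative log2 fold change, against 9 without PKP2_het replicate 3; RYR2, the calcium release channel of the sarcoplasmic reticulum, was at 62.0 ± 24.2 FPKM against 100 ± 24.2 FPKM in WT (limma adjusted p = 0.295). Of 27 sarcomere genes 0 were called and 3 had an unadjusted p under 0.05: TCAP (telethonin) at a log2 fold change of 0.52, LMOD2, a leiomodin of the thin filament, at 0.41 and MYOZ2 (myozenin 2) at 0.34. LMOD2 had a limma adjusted p of 0.319, and 0.0237 without PKP2_het replicate 3. In the list of cardiac stress and fetal genes, 0 of 14 were called and 1 had an unadjusted p under 0.05. ANKRD1, a stretch-responsive gene, had a log2 fold change of -1.03 and a limma adjusted p of 0.307. The members with the next smallest p were FHL1 at 0.41, NPPA at 3.35 ± 1.65 (SE) and CRYAB at 0.33. Their limma adjusted p-values were 0.416, 0.441 and 0.516. In this list 8 log2 fold changes were positive and 6 negative.

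Fibrosis and fat storage genes, which concern tissue changes known in this disease, were not called. In the extracellular matrix list 0 of 38 members passed in limma and 4 had an unadjusted p under 0.05, with 18 positive and 20 negative log2 fold changes. These 4 were MFAP5 at a log2 fold change of 0.44, CTGF at 0.88, LOXL2 at -0.24 and SPARC at -0.39. In the adipogenesis and lipid storage list 0 of 21 members passed, adjusted over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Of these, G0S2 was at a log2 fold change of 0.82 and DGAT2 at 0.51. CFD (adipsin) was at 164 ± 35.8 FPKM against 104.1 ± 12.01 FPKM in WT, with a limma adjusted p of 0.146, and passed only in the list of adipocyte markers when adjusted over the list alone, and AQP7 had a log2 fold change of -0.58. The fatty acid oxidation list had 21 of 29 members with a negative log2 fold change, 16 without PKP2_het replicate 3. It had 0 calls in limma and 3 members with an unadjusted p under 0.05, and its camera adjusted p was 0.106. The list passed camera as lower in 6 alternative settings, with adjusted p = 0.00719 without PKP2_het replicate 1, 0.00957 without PKP2_het replicate 4, 0.0265 without WT replicate 3, 0.00789 with quantile normalisation, 0.0224 with a replicate block and 0.0306 with the length trend removed. Without PKP2_het replicate 3 the list median was -0.017, against -0.14 with all libraries, and the camera adjusted p was 0.632. With all libraries it had adjusted p = 0.961 with an estimated correlation, and 17 of 35 splits, the real one included, gave it as small a camera p. CPT1A and CPT2, the carnitine palmitoyltransferases, had log2 fold changes of -0.65 and -0.47.

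Ribosomal protein, nuclear-encoded oxidative phosphorylation and immediate early genes were the 3 of 36 lists that passed camera, all toward higher levels in PKP2_het, with a preset correlation of 0.01. With an estimated correlation each of the 3 had adjusted p = 0.961. Of 75 ribosomal protein genes 73 had a positive log2 fold change, with a median of 0.25 that turned to -0.020 when libraries were rescaled to equal sums, but 0 were called singly and 2 had an unadjusted p under 0.05; RPLP1 was at 0.46 and RPL10A at 0.42. The median was 0.13 for 75 oxidative phosphorylation genes, or -0.14 after that rescaling, which moved the median of all genes to -0.25. Of these genes 1 was called: ATP5J, a subunit of ATP synthase, rose from 169 ± 6.16 to 286 ± 45.4 FPKM (SD, n = 4; limma adjusted p = 0.0305). The median was 0.30 for 23 immediate early genes, of which 1 was called, and 2 when adjusted over the list alone: IER3 rose from 10.9 ± 2.63 to 20.45 ± 2.499 FPKM, and JUND had a log2 fold change of 0.62. The camera adjusted p was 7.52e-08 for ribosomal proteins, 0.00346 for oxidative phosphorylation and 0.00695 for immediate early genes with the preset correlation. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 14 to 17 gave these lists as small a p, so the list results were not separable from the spread between libraries. Without PKP2_het replicate 3 the median was 0.12 for ribosomal proteins, 0.041 for oxidative phosphorylation and 0.33 for immediate early genes. In the same order, the camera adjusted p was 0.0869, 0.294 and 0.0307. For immediate early genes it was 0.0625 to 0.148 in 4 other fits that left out 1 library.

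Single genes were called in other lists that did not pass camera. SLA-DQB1, a class II histocompatibility gene, fell from 71.2 ± 16.1 to 29.45 ± 7.13 FPKM (SD, n = 4; limma adjusted p = 0.0131), the 1 call among 21 complement and antigen presentation genes. HMOX1, the haem-degrading oxygenase, fell from 2.74 ± 0.303 to 1.33 ± 0.212 FPKM (limma adjusted p = 0.00826), the 1 call among 27 antioxidant and iron genes, whose median log2 fold change was -0.081 and mean 0.016. FRZB was the 1 call among 13 Wnt genes, and WNT9A passed only when adjusted over the list alone. This list had a camera adjusted p of 0.452, or adjusted p = 0.961 with an estimated correlation, a directional fry adjusted p of 0.301 and a fry mixed adjusted p of 0.00697. FRZB is an inhibitor and WNT9A a ligand of the pathway. CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 0.83 and a limma adjusted p of 0.0595, and 0.0195 without PKP2_het replicate 3. Of 33 interferon response genes 0 passed in limma, with a lowest adjusted p of 0.190, and 3 had an unadjusted p under 0.05. Without PKP2_het replicate 3 limma called 2 of them lower, TAP1 (adjusted p = 0.0436) and B2M (gene 397033, adjusted p = 0.0310), both of antigen presentation. In alternative settings SLA-DQB1 lost its call in 3 of 22 (adjusted p up to 0.0890) and HMOX1 in 2 of 21 (up to 0.130).

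No list of markers of other cell types passed camera in the fit reported here. Among endothelial markers 13 of 15 had a negative log2 fold change, with a median of -0.24 and a camera adjusted p of 0.315; CLDN5 was at -0.55 and KDR at -0.40. Without PKP2_het replicate 3 the endothelial median was -0.35 and the camera adjusted p 0.00358, and with an estimated correlation the adjusted p was 0.954. With the preset correlation, camera also gave the endothelial list an adjusted p of 0.0359 without WT replicate 3 and 0.0112 with library quality weights. Other fits weakened it: the median was -0.086 without PKP2_het replicate 1 (camera adjusted p = 0.938) and -0.070 without WT replicate 1 (0.833). Macrophage markers had 12 of 13 members with a negative log2 fold change and a camera adjusted p of 0.315, with CSF1R at -0.51. Without PKP2_het replicate 2 the macrophage median was -0.29 and the camera adjusted p 0.00240. With all libraries and an estimated correlation, both lists had an adjusted p of 0.961, and 25 of 35 splits for endothelial and 19 for macrophage markers, the real one included, gave as small a camera p. LMOD1 was the 1 called gene among 14 pericyte and smooth muscle markers, at 7.32 ± 0.316 FPKM against 4.63 ± 0.747 FPKM in WT (SD, n = 4; limma adjusted p = 0.0346). ATP5J, IER3 and LMOD1 each lost their call in 9 to 12 alternative settings.

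Mitochondrially encoded transcripts differed between single libraries. They made up 33.1 ± 13.7% of fragments in PKP2_het and 27.0 ± 7.18% in WT (SD, n = 4; exact permutation p = 0.571), with 52.1% in PKP2_het replicate 3. Of 13 mitochondrially encoded oxidative phosphorylation genes 10 had a positive log2 fold change, with a camera adjusted p of 0.251. That list passed camera as higher without PKP2_het replicate 1 (adjusted p = 0.0201), without PKP2_het replicate 2 (0.00240), without WT replicate 1 (0.00940) and with libraries rescaled to equal sums (0.000214). Without PKP2_het replicate 3 the shift was gone: 7 of 13 genes were positive and the median was 0.0048, against 0.38 with all libraries. The camera adjusted p was then 0.928, toward lower. With all libraries it had adjusted p = 0.961 with an estimated correlation, and 25 of 35 splits, the real one included, gave it as small a camera p. ATP8, a subunit of ATP synthase, stood at 6.88% and 6.98% of the COX1 level in PKP2_het replicates 3 and 4, and at 0.228% to 0.377% in the other 6 libraries.

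**Figure D3:**
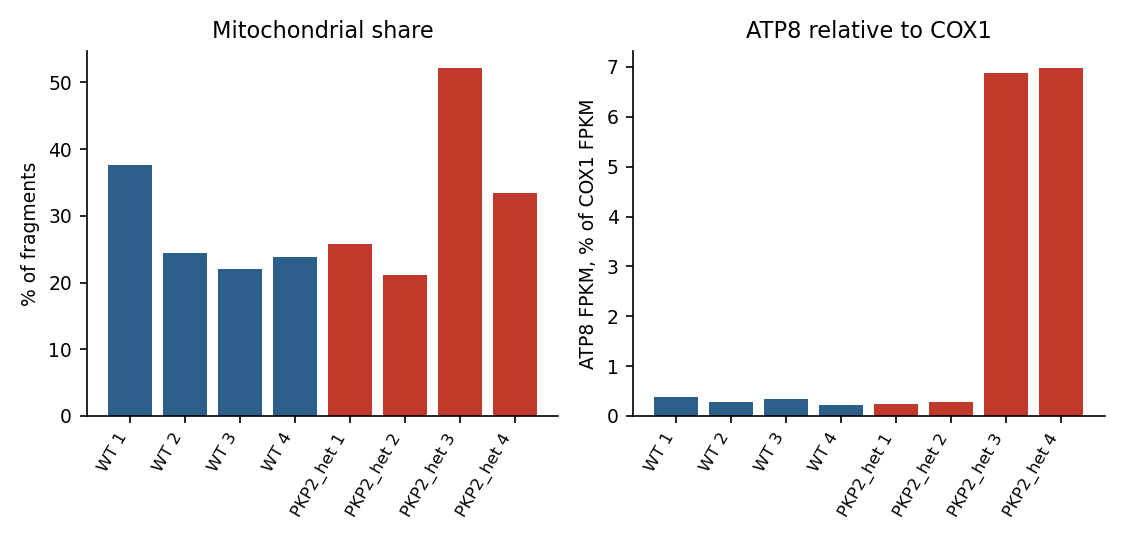
Share of fragments from mitochondrially encoded genes (left, %) and ATP8 FPKM as a percentage of COX1 FPKM (right) in each WT (blue) and PKP2_het (red) library; each bar is 1 library. PKP2_het replicate 3 has the highest share, 52.1%, and ATP8 is high in PKP2_het replicates 3 and 4.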

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

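The tests of PKP2_het replicate 3, of distance to PKP2 and of the mitochondrial share and sequence variant, the setting without PKP2_het replicates 3 and 4, and the minimum of 1 FPKM in the definition of the 26 genes below were chosen after the results were seen. A library was singled out where it lay far from the other 3 of its group on Dixon's ratio at the 95% level, which chance gives in about 1 of 20 groups. Of 250 groups tested 15 met it, close to that share, 5 of them in PKP2_het replicate 3. Across the tested genes, PKP2_het replicate 3 also stood apart. On the first principal component, with 41.6% of the variance, it was at 47.85, against -16.5 to 3.74 in the other libraries. Its mean correlation with its own group was 0.949, against at least 0.970 for every other library. That library had 9.998 FPKM of DSP, 1.49 of DSG2, 8.44 of DSC2, 32.3 of CTNNB1 and 7.05 of SLC8A1, the sodium-calcium exchanger, each below the other PKP2_het libraries. WT replicate 1 had 23637697 fragments (23.6 in units of 1e+06) against 27.6 to 27.9 in the same unit in the other WT libraries, and a mitochondrial share of 37.6%. It also stood above them for ATP8 (295.6 FPKM against 102.8 to 122) and ND3 (6134 FPKM against 3571 to 3771). The steps were smaller for BNIP3L (7.54 FPKM against 5.97 to 6.11) and PRDX1 (23.8 FPKM against 22.15 to 22.29). Single libraries stood apart for DHRSX (6.90 FPKM in WT replicate 4), KCNE1 (47.2 FPKM in PKP2_het replicate 2), HMOX1 (1.64 FPKM in PKP2_het replicate 2) and TBX3 (2.40 FPKM in PKP2_het replicate 1). For DHRSX the step was small, with the other WT libraries at 6.23 to 6.32 FPKM.

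The counts of called genes were not matched by any other grouping of the libraries. Of 35 splits into 4 and 4, only 1, the real one, called as many as 124 genes in the more frequent direction, and only 1 as many as 76 in the other; the highest other split called 0 in limma, with up to 1256 genes at an unadjusted p under 0.05 against 1381 in the real split. The real split thus ranked first for these counts, at 1 in 35, the smallest share that 35 splits can give. The splits treat the libraries as independent, which no label states, so they cannot exclude a shared origin of libraries within a group. For gene lists the real split did not stand out. At least 3 lists passed in 34 of 35 splits, the real one included, and the highest other split passed 18.

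In 26 genes every library of the higher group stood at least 4-fold above every library of the other, with at least 1 FPKM in the higher group (13 in PKP2_het and 13 in WT), and no other split gave any such gene (1 of 35 splits, highest other 0). Linkage to the edited locus is argued against for 16 genes on other chromosomes, and 0% of the 19 placed genes lie within 10 Mb of PKP2, but linkage cannot be told for the 7 on unplaced scaffolds and for 3 on chromosome 5, LOC102167026, CLEC12A and LOC106507545, the nearest of them (LOC102167026) 16.7 Mb and the farthest (LOC106507545) 53.3 Mb from PKP2. That 100% of these genes stayed called without PKP2_het replicate 3 follows from how they were selected and says nothing about the quality of that library. Neighbouring genes of this set changed together more often than in 10000 shuffles, with 4 adjacent pairs against a median of 0. Shared reads between copies or shared haplotypes may produce such pairs. The genes of the set that lie closest together are all on unplaced scaffolds. The carboxylesterase genes LOC100736962, LOC110255234 and LOC110258440 share a scaffold. The V segments LOC110258689 and LOC110258687 and the long noncoding RNA gene LOC110258695 share another. The pairs thus rest on few loci, and these genes may not be separate changes. A genetic background that differs between the groups remains open for all 26 genes, and likewise for all 200 called genes. It cannot be told apart from the knockout, because the labels give no litter or ancestry. TSPO and GGA1 also lie on chromosome 5. Of the 10757 tested genes 59 lie within 10 Mb of PKP2, and 0 of these were called. With 200 calls among all tested genes, 0 among so few says little about linkage.

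The higher level of 3 gene lists was weighed in the same way. Of 35 splits, the real one included, as small a camera p came in 15 for ribosomal proteins, 17 for oxidative phosphorylation and 14 for immediate early genes, so chance cannot be excluded for any of them. For oxidative phosphorylation, both PKP2_het replicate 3 (adjusted p = 0.294 without it) and a trend with gene length (adjusted p = 0.671 once removed, median from 0.13 to -0.013) may account for the shift; the adjusted p was also 0.429 without both replicates 3 and 4, 0.168 without WT replicate 3, 0.344 with quantile normalisation, 0.807 with library quality weights and 0.104 with libraries rescaled to equal sums, so the loss is not specific to either. For ribosomal proteins the adjusted p was 0.0869 without that library but 0.00169 without both replicates 3 and 4, and 0.005325 with the length trend removed, at a median of 0.08, so neither can be told apart from a change in the tissue. For immediate early genes the median was still 0.30 once the length trend was removed (camera adjusted p = 0.00754). This argues against that trend as the whole cause of the shift. Without PKP2_het replicate 3 the median was 0.33, against 0.30 with all libraries. The camera adjusted p was then 0.0307, but 0.954 with an estimated correlation, so the test cannot decide on the part of that library. In other fits the call was lost. The camera adjusted p was 0.147 without both replicates 3 and 4 (median 0.26), and 0.0515 with no filter (0.24). It was 0.145 and 0.0625 without PKP2_het replicates 2 and 4 (0.23 and 0.29), and 0.148 and 0.0758 without WT replicates 3 and 4 (0.19 and 0.29).

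ATP8 was high in PKP2_het replicates 3 and 4 alone. A higher mitochondrial share is argued against: WT replicate 1 had a higher share than PKP2_het replicate 4, yet its ATP8 relative to COX1 was 5.40% of that in PKP2_het replicate 4. In these 2 libraries ATP8 relative to COX1, tRNA-Lys and tRNA-Asn all exceeded 10 times the highest WT library. ND1 was also raised there, at 24.3% and 21.3% of the COX1 level, against 7.57% to 9.42% in the other libraries. A mitochondrial sequence variant that changes where reads align remains a candidate explanation, which cannot be told apart from others without the reads; no biological explanation was tested, since no label separates these 2 libraries.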

How the results depend on the processing

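Without both PKP2_het replicates 3 and 4, and with the trend with gene length removed, are settings added after seeing the data. Between 75 and 195 genes were higher and 40 to 119 lower when single libraries were left out, and 2 to 5 lists passed camera. The highest gene counts came without PKP2_het replicate 3, and the most lists without PKP2_het replicate 1. Of the reported calls, 73 to 119 higher and 39 to 72 lower were kept in these fits, 60 and 35 with a replicate block, and 44 and 38 with libraries rescaled to an equal sum. Without WT replicate 2 there were 77 higher and 42 lower genes, and without WT replicate 4 there were 75 and 40. Lower genes numbered 44, 49 and 50 without PKP2_het replicates 1, 2 and 4. The PKP2 log2 fold change stayed negative, from -0.77 to -0.48 in these fits, with an exact permutation p of 0.0571 without PKP2_het replicate 3 and without WT replicate 4. It was -0.51 without both PKP2_het replicates 3 and 4, where the smallest possible p is 0.0667. In that setting endothelial markers passed as lower (adjusted p = 9.16e-05), and fibroblast (0.00700) and circadian clock genes (0.00759) as higher; with all libraries and an estimated correlation each had an adjusted p of 0.961. A mean of at least 5 FPKM left 39 higher and 28 lower genes, with fewer genes tested, and a minimum log2 fold change of 1 left 63 and 33. Rescaling each library to an equal sum gave 49 higher and 43 lower genes, moved the median of all genes to -0.25, and gave PKP2 a log2 fold change of -0.96 with an exact permutation p of 0.0857. The share of higher genes was then 53.3% of calls, against 62% as reported. Medians turned negative there for ribosomal proteins (-0.020, camera adjusted p = 6.18e-05 toward higher, relative to other genes) and oxidative phosphorylation (-0.14), and for the latter also with library quality weights (-0.0085) and without the length trend (-0.013). Library quality weights gave 367 higher and 292 lower genes; the cause was not tested. With no filter 5 lists passed, among them T and NK cell (adjusted p = 0.00340), neutrophil and mast cell (0.0142) and cell cycle (5.55e-07) genes as lower. With the filter as reported and an estimated correlation 0 lists passed; no estimated correlation was run without the filter. Median-of-ratios scaling moved nothing, because the deposited values already contain it, so it is no independent check. Nothing in the labels says that the replicate numbers pair the libraries. With group means removed, correlations of same-numbered libraries were -0.39, 0.033, -0.23 and 0.20, which cannot exclude a shared litter or batch. A replicate block gave 66 higher and 39 lower genes and 4 lists. No gene called in the reported fit was called in the opposite direction in any setting. Of the alternative values of 120 named genes and list members, 2490 kept their direction and side of the threshold, 67 lost a call, 35 gained one, 19 changed sign without a call and 0 reversed. Most of these genes were not called in the reported fit and had no call to lose. The 2490 therefore does not measure how stable the calls were. Robust variances were not run for camera, which does not take them.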

Other observations

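The transcripts of single libraries below were chosen after their values were seen. Atrial transcripts varied between single libraries. NPPA, the atrial natriuretic peptide gene, was at 373.4 and 87.9 FPKM in PKP2_het replicates 1 and 2 and at 131.5 FPKM in WT replicate 3, and at 16.1 FPKM or less in the other 5 libraries. By group, NPPA was at 121 ± 172 FPKM in PKP2_het and 33.3 ± 65.5 FPKM in WT (SD, n = 4). Its log2 fold change was 3.35 with a standard error of 1.65 and a limma adjusted p of 0.441. Without PKP2_het replicate 3 these were 3.82 and an adjusted p of 0.344, so a group difference in NPPA was neither called nor excluded. MYL7, the atrial myosin light chain, was at 243.2 FPKM in PKP2_het replicate 1 and 1026 FPKM in WT replicate 3, against at most 27.2 FPKM elsewhere. DKK3 was at 37.1 FPKM in PKP2_het replicate 1 and 26.3 FPKM in WT replicate 3, against at most 12.4 FPKM elsewhere. PKP2_het replicate 2 was thus high for NPPA but not for MYL7 or DKK3. The atrial cardiomyocyte list did not differ between the groups by the test used (camera adjusted p = 0.832), with a median log2 fold change of -0.0029 and a mean of 0.37. EIF1AY, on the Y chromosome, was at 18.8 to 30.6 FPKM in all 8 libraries.

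GPX3, a secreted glutathione peroxidase, was at 143 ± 69.8 FPKM in PKP2_het and 50.05 ± 11.5 FPKM in WT (SD, n = 4; limma adjusted p = 0.0640), and passed when adjusted over the list alone, and over all genes without PKP2_het replicate 3 (limma adjusted p = 0.0449). CXCL2, a neutrophil-attracting chemokine, was at 5.50 ± 2.73 and 1.68 ± 1.03 FPKM (limma adjusted p = 0.115). NR1D1, a repressor in the circadian clock, had a log2 fold change of 0.69 and a limma adjusted p of 0.0946, and passed when adjusted over the list alone.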
